A study of Arabidopsis thaliana with 48 samples.

How the data were processed

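Gene expression was measured on 48 1-colour expression arrays of Arabidopsis thaliana, with RNA from isolated guard cells on 24 arrays and RNA from whole leaves on the other 24. Each sample type came from 4 genotypes (the Columbia wild type, WT, a mutant of the heterotrimeric G protein beta subunit, agb1, a mutant of the alpha subunit, gpa1, and the agb1 gpa1 double mutant), each with 50 µM abscisic acid (ABA) for 3 h or with the solvent ethanol (EtOH). That gave 16 groups of 3 arrays, and the labels describe the replicates as independent biological ones. A guard cell sample was drawn from 300 leaves of 60 to 70 plants and a leaf sample from 10 leaves of 3 to 4 plants. Plants were 5 weeks old and grew in 8 h of light at 120 µmol per square metre per second and 16 h of dark, at 20 and 18 °C. The labels differ on whether intact leaves or the isolated guard cells were held in ABA, and the source field gives no treatment where the description gives EtOH. The groups therefore name the ABA or EtOH of the description only.

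The authors processed the arrays with RMA, and the deposited values are log2 expression values per probe set. The submitters' processing notes name RMA and affy, with versions not given in the sources used here, nor whether all 48 arrays were normalized together. Values ran from 2.42 to 14.50 with none missing, array medians from 5.06 to 5.39, and values at a given rank differed between arrays by at most 0.52. Of 22810 probe sets, 64 controls were left out, so that 22746 were tested. A reference table of gene names on the TAIR10.1 assembly tied 13513 probe sets to 1 gene, 503 to several and 8730 to none. Only probe sets tied to exactly 1 gene are named, by symbol or locus, except for a few described by probe set number. Among genes with several probe sets (146), the one with the highest mean over the 48 arrays was named. In no named comparison was another probe set of the gene called in the opposite direction, and directions of uncalled ones were not compared.

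Differences were tested per probe set with limma 3.58.1 in R 4.3.3, on a cell-means model with empirical Bayes moderation. The 27 comparisons were fixed before the data were examined. Those within a sample type used its 24 arrays, and those between sample types used all 48. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 22746 probe sets of a comparison. A probe set counted as called at an adjusted p under 0.05. Differences are log2 values, values per group are mean ± SD with n = 3, and an SE is the moderated one of the fit. A response or effect called higher or lower is so by its signed log2 value. A higher one can thus be a smaller fall, and a lower one a larger fall. Genes are named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest genes without overlap between groups in guard cells against leaves and in each ABA comparison of WT, and 5 of each in other comparisons, plus up to 4 called members of each fixed list. By chance, 10 percent of probe sets show no overlap between groups of 3.

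Gene lists fixed before the data were examined covered ABA-induced genes, ABA synthesis and breakdown, guard cell markers, mesophyll photosynthesis, epidermis, vascular tissue, jasmonate, touch, wound and early stress, heat shock, salicylate and defence, auxin, cell wall loosening, the clock, glucosinolates, flavonoids and partners of the G protein. Lists of 5 or more measured members were tested against all other probe sets with camera at a preset correlation of 0.01, and shorter ones were only counted. Most genes written into the fixed lists had no named probe set, so the tests cover what the annotation left of each list. Measured were 5 of 29 ABA-induced, 5 of 21 touch, 5 of 17 cell wall loosening, 4 of 22 mesophyll, 3 of 16 auxin and 2 of 19 guard cell marker genes. Counts of members below are of measured ones. The fixed lists of clade A PP2C phosphatases, PYR/PYL/RCAR receptors, SnRK2 kinases and guard cell ion transport had 0 named members and were not analysed here. After the data were seen 29 groups were built from the annotation's gene descriptions or locus codes. Those reported on most are the chloroplast-encoded and mitochondrion-encoded genes, nuclear genes of photosynthesis, late embryogenesis abundant (LEA) proteins, autophagy ATG8 genes, ubiquitin-specific proteases, RALF and CLE peptides, UDP-glycosyltransferases, and expansins with xyloglucan hydrolases. The others were glutathione S-transferases, beta-glucosidases, SWEET transporters, trichome birefringence-like genes, aldehyde dehydrogenases, serine carboxypeptidases, AGAMOUS-like and bZIP and WRKY factors, CYP71 enzymes, IQ-domain genes, subtilases, ubiquitin-conjugating enzymes, U-box ligases, RNA polymerase subunits, cellulases, tubulins, tetraspanins, cation exchangers, and IAA with GH3 genes. Of these, tetraspanins passed in 6 comparisons, WRKY factors and ubiquitin-conjugating enzymes in 3 each, aldehyde dehydrogenases in 2, and tubulins and SWEET transporters in 1 each, none of them with an estimated correlation. A group of nuclear genes of mitochondrial respiration was added last. It was a family of 1 list, so its p-values are unadjusted. In all, 891 list tests were made on 33 lists in 27 comparisons, adjusted within each comparison and family of lists. Of these, 127 passed at the preset correlation and 10 of them also with the correlation estimated from the data. Among them were 14 and 1 tests of the respiration group, at unadjusted p-values. Camera tests the mean of moderated statistics, so that a list's median difference can be small or of another sign than the test.

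Replicate numbers were taken from the labels. The EtOH and ABA arrays of 1 genotype with the same number were correlated beyond 0.1, after group means were removed, in 12 of 12 pairs of guard cell arrays (0.204 to 0.644) and in 7 of 12 pairs of leaf arrays (-0.359 to 0.661), among them all of agb1. Between WT and mutants this held in 6 of 18 and 5 of 18 pairs, and between guard cells and leaves in 4 of 24. A fit with the replicate number within genotype as a block was added after the data were seen, and in it 5358 probe sets were called for ABA in agb1 guard cells against 3571 without pairs.

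Alternatives set before the data were examined were 1 fit of all 48 arrays, a fit of only the groups compared, the replicate number as a block, probe sets in the lowest 40 percent of mean signal left out, quantile normalization, median centring, trend and robust moderation, array weights, 1 probe set per gene, genotype effects averaged over both treatments, and each array left out in turn. For lists they were an estimated correlation, the fry test, dim probe sets left out and the block. Leaving out each array in the list tests was added after the data were seen. Calls were also counted for other splits of the same arrays, all 10 where 2 groups were compared and otherwise 100 drawn ones. Pairs of mutant effects share WT arrays, so their correlation was set against 100 simulated draws without any effect. For effects that share no WT array, the EtOH and ABA arrays of the same number were drawn as pairs, a choice made after the data were seen. The score of the ABA response was, per array, the mean over the probe sets called in WT guard cells of the deviation from the 48-array mean, signed by the WT guard cell response. An interval of a list's median was taken from the ordered members by the sign test.

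The procedure was tested on simulated data with 100 of 22746 probe sets changed by 1 and 100 by 2 on the log2 scale, at the spread of the real arrays. It recovered 68 and 97 for guard cells against leaves, 74 and 98 for ABA in WT guard cells, 73 and 91 for ABA in WT leaves, 59 and 98 for agb1 against WT in leaves, 48 and 86 for the difference of the ABA response in guard cells of gpa1, and 41 and 86 in leaves. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Probe sets named for AGB1, GPA1, RD29A, RD29B, RAB18, HAI1, NCED3 and ABI1 were lacking in the reference table, and these genes were not analysed here. Sequence variants and proteins were not analysed here.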

Results

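The 48 arrays compared guard cells with whole leaves, ABA with solvent, and WT with mutants of the G protein alpha (gpa1) and beta (agb1) subunits. Each of the 16 groups held 3 arrays. The results are given first for the 2 sample types of WT, then for ABA in each, and last for the mutants.

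Several single genes lay far apart between guard cell samples and leaves of WT without ABA. AT1G54050, a small heat shock protein, was higher in guard cells by 8.22 (SE 0.324), at 12.43 ± 0.17 against 4.21 ± 0.29 (adjusted p = 3.83e-21). AT5G51440, another small heat shock protein, was higher by 7.95, the expansin EXPA16 by 7.75 and AT5G48570, a prolyl isomerase of the heat shock response, by 7.12. The stomatal lineage regulator FMA (FAMA), 1 of 2 measured guard cell markers, was higher by 5.05 (10.93 ± 0.63 against 5.88 ± 0.55, adjusted p = 5.16e-17), while MUTE, another regulator of that lineage, stood at -0.24 (adjusted p = 0.0585) and was lower only when adjusted over the list alone. The sucrose exporter SWEET11, the vascular marker, was lower in guard cells (-6.32, 4.76 ± 0.62 against 11.08 ± 0.30), as were the calmodulin-like CML41 (-6.68) and ECS1 (-7.17).

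Genes of the photosynthetic apparatus were lower in guard cells. Here and below, groups from the annotation and the members named from them were chosen after the values were seen. All 4 measured mesophyll genes passed, among them SBPASE, an enzyme of the Calvin cycle (-2.42), LHCB4.2, a light-harvesting protein (-2.11), and RCA, the rubisco activase (-1.78). In the annotation group of nuclear photosynthesis genes 20 of 23 were lower and 1 higher (PGRL1B, 2.15-fold), with PRK at -3.38 and PSAN at -4.03. Its median difference was -2.22 (camera adjusted p = 1.92e-11, but adjusted p = 0.129 with an estimated correlation). Transcripts of the 2 organelle genomes parted. Of 15 mitochondrion-encoded genes 14 were higher in guard cells, with nad6 at 5.74, nad5 at 4.50 and cox1 at 4.35, and nad2 (-0.17) did not pass. Their median was 3.93 (adjusted p = 4.9e-12, and adjusted p = 0.116 with an estimated correlation). Of 69 chloroplast-encoded genes 33 were lower and 6 higher, the latter including rps14 (5.13) and rbcL (1.58), with a median of -0.71 (adjusted p = 0.0118, and adjusted p = 0.798 with an estimated correlation). The chloroplast call was lost without leaf EtOH replicate 3 (adjusted p = 0.0778) and without dim probe sets (adjusted p = 0.0788). Nuclear genes of mitochondrial respiration were higher in 8 of 14 cases and lower in 1, with CYTC-2, a cytochrome c, at 2.94 and a median of 0.48. Camera gave them p = 0.00106, and p = 0.0357 with an estimated correlation, both unadjusted.

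**Figure D1:**
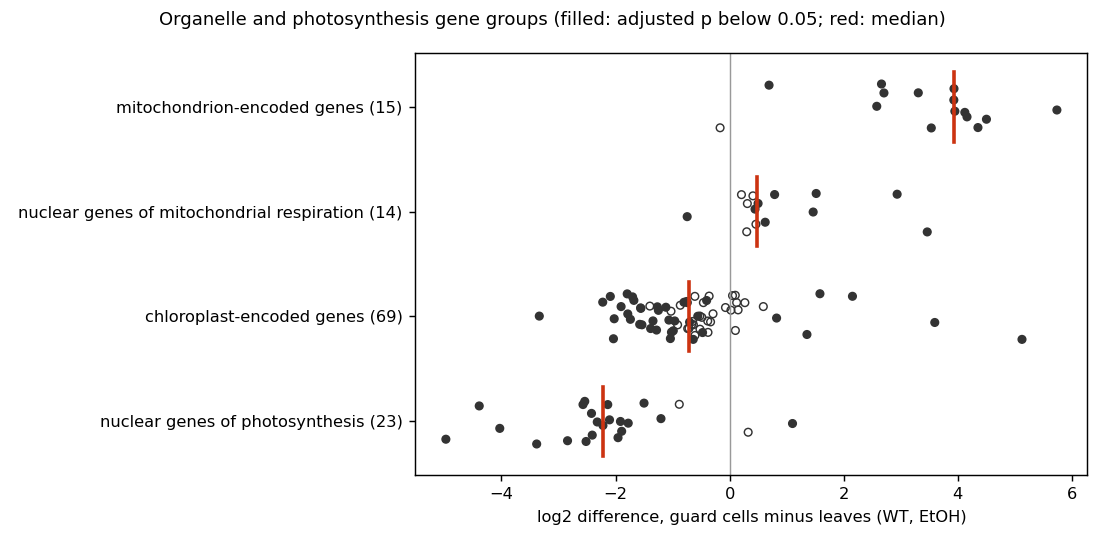
Log2 difference of guard cells minus leaves in WT without ABA (horizontal axis) for each gene of 4 groups, with the number of genes in brackets; each point is 1 gene from 3 arrays per sample type, filled where its adjusted p was under 0.05, and red bars are medians. Mitochondrion-encoded genes lay around a median of 3.93 and nuclear photosynthesis genes around -2.22.

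The touch, wound and early stress list was higher in guard cells in 4 of its 5 measured genes and lower in 1 (WRKY53, -1.42). The calmodulin-like genes CML23 (5.23), CML37 (4.12) and CML38 (3.47) and the zinc finger gene STZ (3.44) were higher (adjusted p = 7.43e-04 for the list, and adjusted p = 0.0354 with an estimated correlation, median 3.47). Auxin response genes were lower in 3 of 3 cases (GH3.3 -3.25, WES1 -2.27, IAA29 -1.89). ABA-induced genes split, with LEA4-5 at 3.42 and COR15A at -3.47 and 3 of 5 not passing, and cell wall loosening genes split as well (XTH16 2.62, XTH33 -2.31, 3 of 5 not passing). Single measured members were lower for salicylate and defence (SAG101, -2.19) and for partners of the G protein (PRN, a pirin, -2.07). Lower too were jasmonate (PDF1.2, a defensin, -2.31, adjusted p = 0.0277) and glucosinolates (BCAT4, which acts early in methionine chain elongation, -2.67, adjusted p = 0.0144). PDF1.2 kept its call only when leaf EtOH replicate 3 was the array left out (adjusted p of 0.0627, 0.0529 and 0.0611 without guard cell EtOH replicates 1, 2 and 3, and 0.22 and 0.106 without leaf EtOH replicates 1 and 2). BCAT4 lost its call without guard cell EtOH replicate 2 (0.0645) or leaf EtOH replicate 1 (0.214). The single heat shock member was AT5G48570, 1 of 2 flavonoid genes was higher (UF3GT, 0.94), and the measured gene passed in none of ABA synthesis, epidermis and clock.

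In all, 4548 probe sets were higher and 5043 lower in guard cells, 9591 of 22746, and groups did not overlap at 52.2 percent against 10 percent by chance. Under median centring the split became 8100 higher and 4122 lower, since that scaling moved the median of all probe sets from 0.04 to 0.25, a shift of 0.21. Relative to that scaling the lists kept their sign, with medians of 4.14 for mitochondrion-encoded, -0.50 for chloroplast-encoded, -2.01 for nuclear photosynthesis, 0.69 for respiration and 3.68 for touch genes. Isolation of guard cells went with the sample type, so that the comparison holds both.

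Genes of the late embryogenesis abundant type were among those that ABA raised most in WT guard cells. The LEA family gene AT3G02480 rose by 7.97 (SE 0.409), from 4.01 ± 0.12 to 11.98 ± 0.38 (adjusted p = 4.09e-11), AT3G17520, also of the LEA type, by 7.31, AT5G45690 by 6.78 and LEA18 63.8-fold. AT4G21870, a small heat shock protein, fell by 5.31 (10.03 ± 0.10 to 4.72 ± 0.80, adjusted p = 5.57e-09), AT5G44680 fell by 5.28 and AT5G62360 fell by 4.86. The guard cell regulator FMA fell by 2.44 (adjusted p = 1.41e-06). Cell wall genes moved both ways, with the expansin EXPA4 rising by 3.76 and the xyloglucan hydrolase XTH16 at -3.04.

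The fixed list of ABA-induced genes rose in 4 of 5 measured members of the 29 written, and in 4 when adjusted over the list alone. They were COR15A (4.77), LEA4-5 (4.25), LTI30 (2.00) and COR47 (1.43), all cold or dehydration proteins. The list's adjusted p was 4.11e-05, and adjusted p = 0.0722 with an estimated correlation. Of the 17 genes of the LEA annotation group 8 rose and 9 did not pass (adjusted p = 1.22e-04, and adjusted p = 0.223 with an estimated correlation). The median was 0.35. Nuclear photosynthesis genes fell in 8 of 23 cases (PORB -1.98, CHLM -1.23, both of chlorophyll synthesis; adjusted p = 0.00334, and adjusted p = 0.542 with an estimated correlation). That call was lost without guard cell EtOH replicate 1 (adjusted p = 0.0513) and without dim probe sets (adjusted p = 0.0685). No chloroplast-encoded gene of 69 was called by limma, though camera gave the list an adjusted p of 0.00702 (adjusted p = 0.917 with an estimated correlation). Of the mesophyll list LHCB4.2 fell (-1.56) and 3 of 4 did not pass. WRKY factors fell in 2 of 6 cases (adjusted p = 0.0199, and adjusted p = 0.24 with an estimated correlation). Ubiquitin-conjugating enzymes rose in 2 of 12 (adjusted p = 0.0252, and adjusted p = 0.459 with an estimated correlation), a call lost in 2 of 6 fits with an array left out (up to 0.0712).

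PRN, the measured partner of the G protein, rose by 2.86, UGT71B6, a glucosyltransferase acting on ABA, by 1.64 and WES1, an auxin conjugating enzyme and 1 of 3 auxin genes, by 3.22. In the touch list CML37 rose (1.28, adjusted p = 0.0123) and 4 of 5 did not pass, and 2 fell when adjusted over the list alone. The flavonoid gene DFR rose by 0.37 (adjusted p = 0.0203). CML37 lost its call without guard cell EtOH replicate 1 (adjusted p = 0.0542) or 2 (0.0701), and DFR without EtOH replicate 2 (0.119), ABA replicate 2 (0.0593) or ABA replicate 3 (0.0941). The single measured genes of vascular tissue, epidermis, jasmonate, heat shock, salicylate, clock and glucosinolates did not pass.

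ABA in WT guard cells gave 1944 higher and 2641 lower probe sets, 4585 in all, of which 1069 and 1008 changed at least 2-fold. Groups did not overlap at 32.2 percent of probe sets, against 10 percent by chance. In a fit of only the 6 arrays compared the count was 3017.

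In WT leaves the LEA family gene AT3G02480 again rose most, by 7.56 (3.59 ± 0.18 to 11.15 ± 0.31, adjusted p = 9.14e-10). AT3G22620, of the lipid transfer type, rose by 6.30, AT5G39520 by 6.28 and PUB19, a ubiquitin ligase, by 5.98. AT4G21870 fell by 5.02 (adjusted p = 9.36e-09). Among the 10 lowest genes were the chloroplast-encoded rpl22 (-4.27), psaA of photosystem I (-3.99, 11.67 ± 0.73 to 7.67 ± 0.27), rpl36 (-3.97) and rps3 (-3.56). FMA fell by 1.12 (adjusted p = 0.00372).

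ABA-induced genes rose in 3 of 5 cases, also when adjusted over the list alone (LEA4-5 4.32, COR15A 2.18, LTI30 1.68). The list's adjusted p was 0.0119, and adjusted p = 0.0289 with an estimated correlation. LEA group genes rose in 9 of 17 cases (adjusted p = 5.21e-04, and adjusted p = 0.117 with an estimated correlation). ATG8 genes, whose products build autophagosomes, rose in 7 of 9 cases (ATG8B 2.61, APG8A 2.04), with a median of 1.72 (adjusted p = 1.48e-04, and adjusted p = 0.506 with an estimated correlation). Ubiquitin-specific proteases fell in 8 of 12 cases (UBP23 -2.45, UBP15 -1.95), with a median of -1.13 (adjusted p = 0.00165, and adjusted p = 0.506 with an estimated correlation). Tetraspanins rose in 4 of 15 cases (adjusted p = 0.0143, and adjusted p = 0.506 with an estimated correlation), and the list passed in every fit with an array left out. RALF and CLE peptide genes rose in 7 of 17 cases (RALFL32 3.41, CLE44 2.32; adjusted p = 0.00665, and adjusted p = 0.506 with an estimated correlation). Expansins and xyloglucan hydrolases rose in 6 of 27 cases and fell in 1 (EXPA16 4.72, XTH19 3.75; adjusted p = 0.0327, and adjusted p = 0.506 with an estimated correlation), a call lost without EtOH replicate 1 (0.0747) or 2 (0.0555) or ABA replicate 1 (0.052).

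Nuclear photosynthesis genes fell in 12 of 23 cases (PORB -2.32, PRK -2.19), with a median of -1.01 (adjusted p = 0.00165, and adjusted p = 0.506 with an estimated correlation). In the mesophyll list 3 of 4 fell (SBPASE -2.07, RCA -1.92, LHCB4.2 -1.01). Chloroplast-encoded genes fell in 24 of 69 cases and rose in 5 (adjusted p = 0.0146, and adjusted p = 0.597 with an estimated correlation). Without leaf EtOH replicate 3 that call was lost (0.119), as it was without dim probe sets (0.192). Mitochondrion-encoded genes rose in 5 of 15 cases (adjusted p = 0.0484, and adjusted p = 0.517 with an estimated correlation), a call lost without EtOH replicate 1 (0.104) or ABA replicate 1 (0.105). Respiration genes rose in 9 of 14 cases and fell in 2 (unadjusted camera p = 0.00824, and unadjusted p = 0.135 with an estimated correlation).

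The touch list rose in 4 of 5 cases and fell in 1, with the calmodulin-like CML37 at 3.54, CML23 at 2.75 and CML38 at 1.94 and STZ at 1.34 (adjusted p = 0.0127, and adjusted p = 0.139 with an estimated correlation). Single genes fell for the clock (GI, -1.83), vascular tissue (SWEET11, -1.24) and salicylate and defence (SAG101, -1.40), and PRN rose by 1.21. DFR rose by 0.37 (adjusted p = 0.0281) and IAA29, 1 of 3 auxin genes, fell by 1.61 (adjusted p = 0.0474), though no auxin gene passed over the list alone. IAA29 passed in only 1 of 6 fits with an array left out (adjusted p of 0.189 and 0.0629 without EtOH replicates 1 and 3, and 0.0738, 0.0684 and 0.14 without ABA replicates 1, 2 and 3). DFR lost its call without EtOH replicate 1 (0.0984) or 3 (0.0628) or ABA replicate 2 (0.0847) or 3 (0.111). The measured genes of jasmonate and ABA synthesis rose only at an unadjusted p under 0.05 by limma, since each list held 1 measured member. They were not called. No measured gene passed for cell wall loosening, epidermis, heat shock and glucosinolates.

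ABA in WT leaves gave 3848 higher and 4964 lower probe sets, 8812 in all, with no overlap at 48.9 percent against 10 percent by chance. Median centring made this 9231 higher and 3821 lower, as it moved the median of all probe sets from 0.05 to 0.31, a shift of 0.25. Relative to it the list medians were 1.93 for ABA-induced, 1.32 for LEA, 1.97 for ATG8, -0.88 for ubiquitin-specific protease, -0.76 for nuclear photosynthesis, -0.08 for chloroplast-encoded and 2.2 for touch genes.

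Guard cells and leaves of WT shared part of the response. Higher in both were 841 probe sets, with 328.9 expected by chance, and lower in both 1347, with 576.4 expected, while 394 went opposite ways (correlation 0.432). The difference of the response between the sample types was tested directly. AT3G17520 responded more in guard cells by 6.40 (adjusted p = 1.23e-08), at 10.95 ± 0.08 with and 3.63 ± 0.06 without ABA there. AT5G45690 responded more by 5.81, EXPA4 by 3.61 and PRN by 1.65. AT5G39520 responded more in leaves (-5.80, 10.04 against 3.76 there and 4.01 against 3.53 in guard cells), as did AT3G14280 (-5.10). The sugar transporter SWEET4 (-4.68) did too, at 9.35 ± 1.02 with and 4.47 ± 0.92 without ABA in leaves and at 4.11 ± 0.21 and 3.92 ± 0.12 in guard cells. XTH16 differed by -3.52, as it fell in guard cells and did not pass in leaves.

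In the touch list 4 of 5 genes had the lower response in guard cells (CML23 -3.28, CML38 -2.43, STZ -1.62), with a median of -2.25 (adjusted p = 3.23e-04, and adjusted p = 0.0244 with an estimated correlation). CML23 stood at 9.81 in guard cells without ABA and 9.27 with it, against 4.58 and 7.33 in leaves. ATG8 genes had the lower response in guard cells in 7 of 9 cases (median -1.46, adjusted p = 4.14e-05, and adjusted p = 0.42 with an estimated correlation). Ubiquitin-specific proteases had the higher one in 7 of 12 (median 1.06, adjusted p = 0.00338, and adjusted p = 0.42 with an estimated correlation). Respiration genes had the lower one in 8 of 14 (unadjusted camera p = 0.00354, and unadjusted p = 0.0594 with an estimated correlation).

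The response was higher in guard cells at 2803 probe sets and lower at 2430, 5233 in all. Of these 966 were called for ABA in guard cells alone, 3150 in leaves alone, 485 in both with the same direction and 394 in opposite directions, and 238 in neither. Median centring moved the split to 2043 and 3468, and the median of all probe sets from 0.01 to -0.19, a shift of 0.2. Relative to it the list medians were -2.45 for touch, -1.66 for ATG8 and 0.86 for ubiquitin-specific protease genes.

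**Figure D2:**
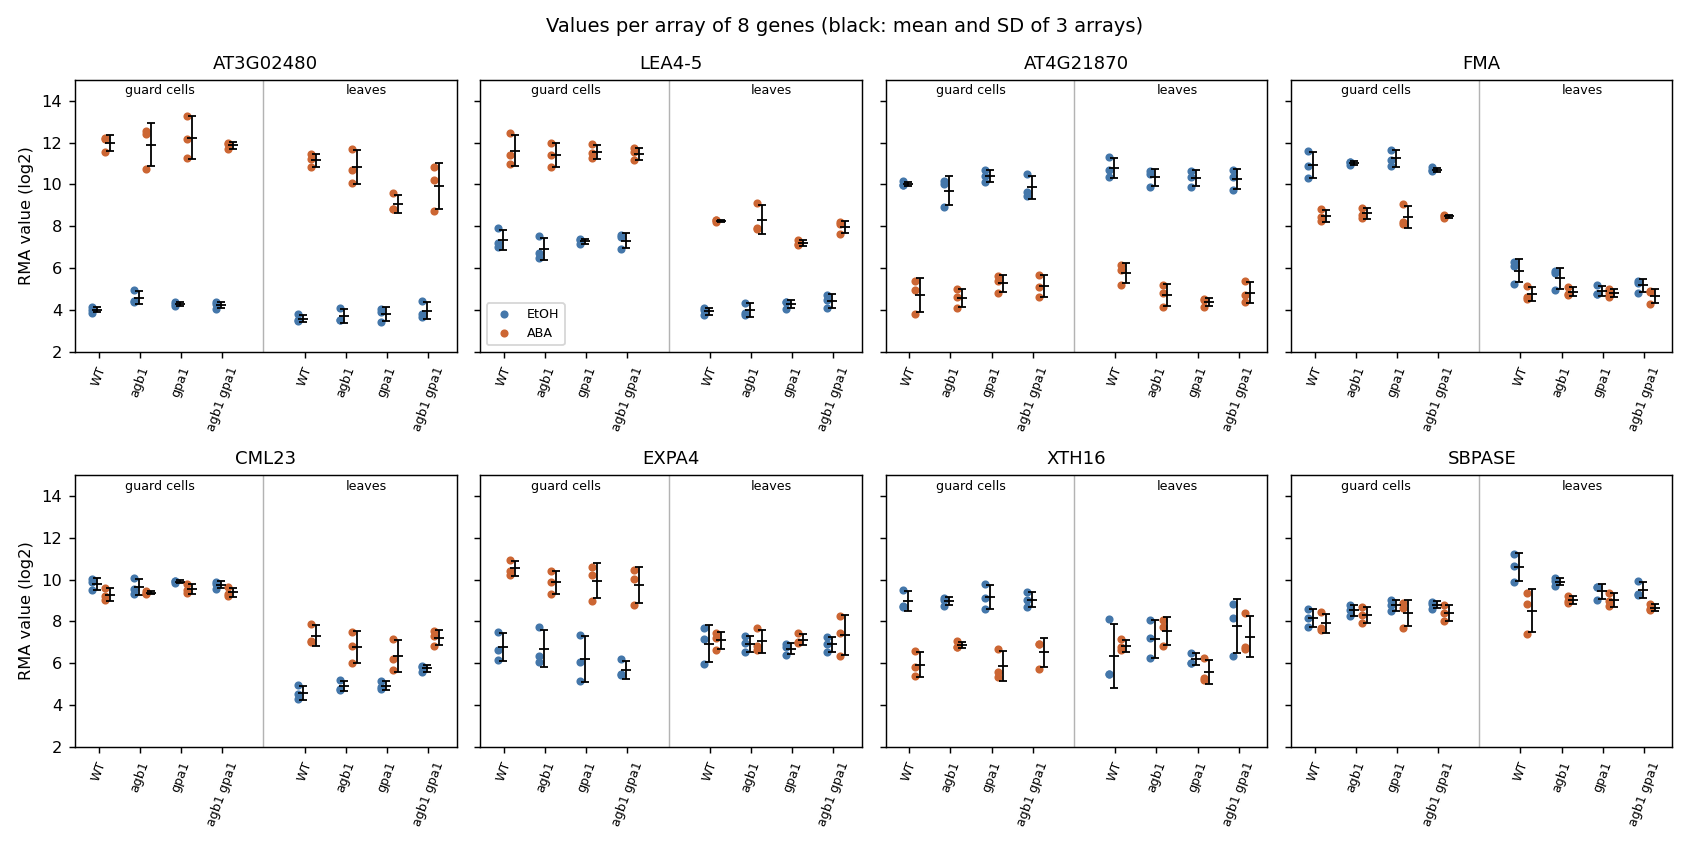
Deposited RMA values (log2, vertical axis) of 8 genes on each of the 48 arrays, by genotype and sample type, with solvent arrays in blue and ABA arrays in orange; each point is 1 array and black bars are mean and SD of 3. AT3G02480 rose with ABA in WT (from 4.01 to 11.98 in guard cells and from 3.59 to 11.15 in leaves), while EXPA4 rose in guard cells of WT from 6.77 to 10.53 and stood at 6.94 and 7.09 in leaves.

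Several genes that ABA moved in WT guard cells moved in the mutants too. AT3G02480 rose by 7.32 in agb1, 7.95 in gpa1 and 7.64 in the double mutant, and LEA4-5 by 4.50, 4.28 and 4.16. AT4G21870 fell in each (-5.13, -5.14 and -4.73) and so did FMA (-2.40, -2.78 and -2.24). EXPA4 rose by 3.17, 3.74 and 4.05, XTH16 fell (-2.09, -3.30 and -2.52), and PRN rose by 2.48, 2.75 and 2.88. The fixed ABA-induced list rose in 4 of 5 members in each mutant, and in 4 when adjusted over the list alone (adjusted p = 9.73e-05, 4.4e-04 and 3.62e-04, and adjusted p = 0.0901, 0.135 and 0.128 with an estimated correlation). LEA genes rose in 9, 9 and 8 of 17 (adjusted p = 1.46e-05, 9.8e-05 and 9.8e-05, and adjusted p = 0.124, 0.209 and 0.209 with an estimated correlation). Calls numbered 3571 in agb1 (1651 higher), 4564 in gpa1 (1971 higher) and 3695 in the double mutant (1651 higher). Median centring turned the split to 1788 higher and 1587 lower in agb1 and to 1862 and 1630 in the double mutant, moving the all-gene medians by 0.051 and 0.0627. With the replicate number within genotype as a block, added after the data were seen, agb1 gave 5358. Higher in all 4 genotypes were 1225 probe sets and lower 1332, and responses of pairs of genotypes correlated at 0.936 to 0.951.

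In leaves of the mutants PUB19, EXPA16 and AT5G39520 were among the genes that ABA raised most. The first rose by 6.34 in agb1, 6.15 in gpa1 and 6.12 in the double mutant, the second by 5.47, 5.54 and 5.70, and the last by 5.93, 6.06 and 5.60. AT4G21870 fell (-5.63, -5.91 and -5.44), and LEA4-5 (4.32, 2.91 and 3.54) and COR15A (2.25, 1.96 and 2.11) rose. The call of COR15A in agb1 ended in a fit of only the groups compared (adjusted p = 0.0847). ABA-induced genes rose in 3, 4 and 3 of 5 cases, and in all 5 when adjusted over the list alone (adjusted p = 6.53e-06, 1.46e-06 and 4.4e-06, and adjusted p = 5.53e-04, 3.01e-04 and 4.69e-04 with an estimated correlation). LEA genes rose in 7 of 17 in each (adjusted p = 1.07e-06, 5.52e-06 and 4.07e-07, and adjusted p = 0.0112, 0.0185 and 0.00845 with an estimated correlation). Calls numbered 3303 in agb1 (1576 higher), 2347 in gpa1 (1221 higher) and 2311 in the double mutant (1157 higher), against 8812 in WT. Without leaf EtOH replicate 1 or ABA replicate 3 agb1 gave 2197 and 2166, and without ABA replicate 3 gpa1 gave 1439 and the double mutant 1404. Fits of only the groups compared gave 1557, 3967 and 1358, and array weights gave 5806 for gpa1. Median centring made the split 1962 higher and 1281 lower in agb1 and 1379 and 829 in the double mutant, with all-gene medians of 0.12 and 0.11.

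Higher with ABA in leaves of all 4 genotypes were 854 probe sets and lower 665, and responses of pairs of genotypes correlated at 0.754 to 0.948. In all 8 ABA comparisons 344 were higher and 191 lower.

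**Figure D3:**
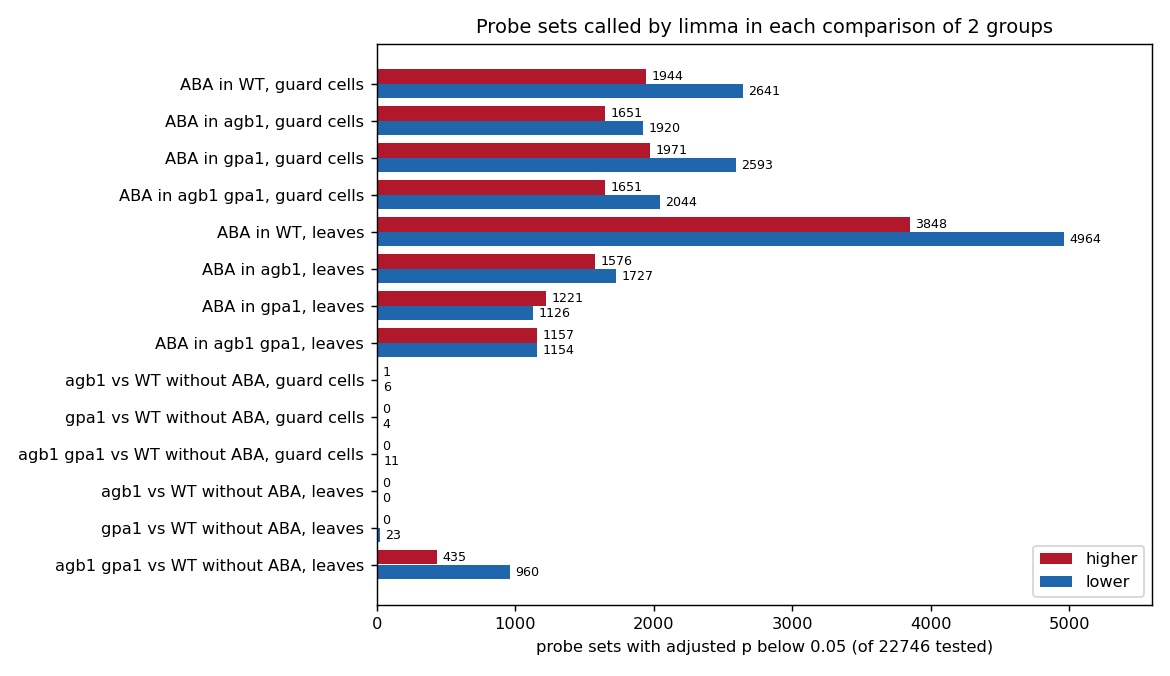
Number of probe sets called by limma (adjusted p under 0.05, horizontal axis) as higher (red) or lower (blue) in 14 comparisons of 2 groups of 3 arrays; each bar is a count out of 22746. ABA in WT leaves gave 3848 higher and 4964 lower.

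Despite these counts, no single gene passed the direct test of a different ABA response in a mutant, while some gene groups did at the preset correlation. Limma called 0 probe sets for agb1, gpa1 and the double mutant in guard cells, with 308, 519 and 476 at an unadjusted p under 0.05. It called 0 of each in leaves as well, with 2805, 5013 and 3825 unadjusted and lowest adjusted p-values of 0.198, 0.0616 and 0.1. The leaf counts of 0 depended on the fit: with all 48 arrays they were 5, 1392 and 493, with only the groups compared 1758 for gpa1 and 255 for the double mutant, with array weights 28, 5009 and 1255, and with a replicate block within genotype, added after the data were seen, 5, 921 and 6. Leaving out agb1 ABA replicate 3 gave 180 for agb1. For gpa1 the count was 766 without gpa1 EtOH replicate 3, 2 without WT EtOH replicate 2 or WT ABA replicate 2 and 5 without WT ABA replicate 1, and for the double mutant 1 without WT ABA replicate 3 or its own ABA replicate 2. In guard cells agb1 gave 1 without agb1 EtOH replicate 1. Median centring moved the all-gene medians of the 3 leaf tests by 0.131, 0.18 and 0.149.

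Of 33 lists 5, 9 and 9 passed these direct tests in leaves of agb1, gpa1 and the double mutant and 1, 2 and 0 in guard cells, and none passed with an estimated correlation. ATG8 genes had the lower response in mutant leaves, with medians of -0.73, -0.79 and -0.74 (adjusted p = 4.41e-04, 0.00199 and 3.57e-04, and adjusted p = 0.849, 0.537 and 0.686 with an estimated correlation). Ubiquitin-specific proteases had the higher one, with medians of 0.72, 0.92 and 0.83 (adjusted p = 3.69e-04, 5.09e-04 and 2.15e-04, and adjusted p = 0.849, 0.537 and 0.686 with an estimated correlation). No member of the 2 groups passed by itself, and both groups passed in every fit with an array left out. The tests of the mutants share the WT leaf arrays, so their agreement is not independent. Relative to median centring the medians were -0.87, -0.97 and -0.89 for ATG8 genes and 0.59, 0.74 and 0.68 for ubiquitin-specific proteases. Chloroplast-encoded genes had the higher response in double mutant leaves, with the lowest p of the lists there (median 0.37, adjusted p = 1.49e-04, and adjusted p = 0.686 with an estimated correlation) in every fit with an array left out, and passed in agb1 (adjusted p = 0.0192) and gpa1 (adjusted p = 0.00255), where the call was lost in 4 and 2 of 12 such fits. The estimated correlation gave adjusted p = 0.849 and 0.663 for them. Tetraspanins had the lower response in gpa1 (median -0.36, adjusted p = 0.00255, and adjusted p = 0.537 with an estimated correlation) in every such fit. The fixed touch list had the lower one in the double mutant (median -0.83, adjusted p = 0.0223, and adjusted p = 0.264 with an estimated correlation), a call lost in 5 of 12 such fits (up to 0.159). In guard cells the lists were chloroplast-encoded genes (agb1, adjusted p = 3.11e-04, gpa1, adjusted p = 4.45e-05, and adjusted p = 0.773 and 0.9 with an estimated correlation) and mitochondrion-encoded genes (gpa1, adjusted p = 0.00489, and adjusted p = 0.9 with an estimated correlation), lost in 4, 3 and 4 of 12 such fits.

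On a score over the probe sets called for ABA in WT guard cells, guard cells of WT moved from -0.478 ± 0.0249 to 0.718 ± 0.0882 (n = 3), a response of 1.2, and those of agb1, gpa1 and the double mutant by 1.05, 1.12 and 1.01. Leaves moved by 0.693 in WT, 0.619 in agb1, 0.532 in gpa1 and 0.529 in the double mutant. In leaves without ABA the score was lower in WT (-0.465 ± 0.031) than in agb1 (-0.372 ± 0.0895), gpa1 (-0.356 ± 0.0205) and the double mutant (-0.325 ± 0.0318). WT differed from the 9 mutant arrays by -0.114 (exact permutation p = 0.00909 over 220 splits, adjusted p = 0.0364 over 4 such tests). With ABA the leaf difference was 0.0193 (exact permutation p = 0.614). In guard cells it was -0.017 without (exact permutation p = 0.55) and 0.116 with ABA (exact permutation p = 0.136).

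**Figure D4:**
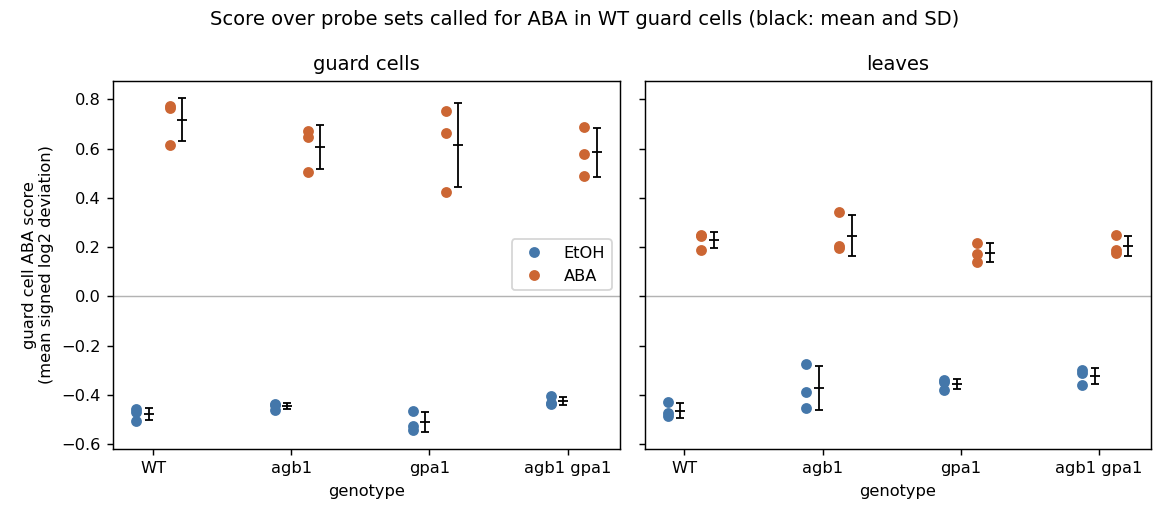
Score of the guard cell ABA response (mean signed log2 deviation, vertical axis) by genotype in guard cells and leaves, solvent in blue and ABA in orange; each point is 1 array and black bars are mean and SD of 3. The probe sets were chosen on WT guard cells, which favours a large response there; mutant leaves without ABA lay above WT leaves (-0.372, -0.356 and -0.325 against -0.465).

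The targeted genes AGB1 and GPA1 had no probe set named for them and were not analysed here. Probe sets without a gene name, picked after their values were seen, separated the genotypes. Probe set 267375_at was lower than WT in gpa1 (-4.33 in guard cells, adjusted p = 3.84e-09, and -4.27 in leaves, adjusted p = 1.7e-08) and in the double mutant (-4.73 and -4.33). In agb1 it stood at -0.35 and 0.22 from WT, not passing. Probe set 253204_at was lower in agb1 guard cells (-2.86, adjusted p = 9.75e-09) and in the double mutant (-4.57 in guard cells and -4.01 in leaves), with agb1 leaves at -1.79 (adjusted p = 0.201). Probe set 253271_s_at was higher in agb1 guard cells (4.14, adjusted p = 1.48e-06) and stood at 0.13 in those of the double mutant (adjusted p = 0.997) and at 1.39 in agb1 leaves (adjusted p = 0.523).

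Few other genes separated the mutants from WT in guard cells without ABA. AT1G63750, a resistance protein of the TIR-NBS-LRR class, was lower in gpa1 (-2.02, 3.83 ± 0.20 against 5.84 ± 0.21, adjusted p = 6.62e-06) in every fit with an array left out. It stood at 0.08 in agb1 and at -0.22 in the double mutant (adjusted p = 0.953). AT2G22320 was lower in agb1 (-2.24, 4.90 ± 0.22 against 7.14 ± 0.70, adjusted p = 0.00816) and in the double mutant (-2.36, adjusted p = 0.00536), and AT4G15975, a ring finger protein, in both (-1.45, adjusted p = 0.0254, and -1.60, adjusted p = 0.00815). The berberine bridge enzymes AT1G30700 (-2.84, adjusted p = 0.042) and AT1G26380 (-2.66, adjusted p = 0.0358) were lower in gpa1. Calls were lost in 2 of 6 fits with an array left out for AT2G22320 in agb1, 4 for AT4G15975 in agb1 and 2 in the double mutant, 6 for AT1G30700 and 5 for AT1G26380, with adjusted p up to 0.387. Fits of only the groups compared ended the calls of AT2G22320 (0.485 in agb1, 0.279 in the double mutant), AT4G15975 (0.984 and 0.279) and AT1G26380 (0.239).

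Limma called 7 probe sets in agb1 (1 higher), 4 in gpa1 and 11 in the double mutant (0 higher) in guard cells, with 795, 1630 and 1405 at an unadjusted p under 0.05. No overlap was seen at 9.7, 12.1 and 14.2 percent against 10 percent by chance. Without WT EtOH replicate 3 agb1 gave 3. The gpa1 count was 2 without any 1 of WT EtOH replicates 1 and 3 and gpa1 EtOH replicates 1 and 3. The double mutant gave 17 and 5 without WT EtOH replicates 1 and 3 and 7, 6 and 5 without its own replicates 1, 2 and 3. Averaging over both treatments gave 25, 47 and 133. That fit took the EtOH and ABA arrays of a genotype as independent, although those of the same number were correlated in guard cells. Array weights gave 16, 13 and 184, and a fit of all 48 arrays 9 for gpa1. Only the groups compared gave 2, 8 and 2. For the double mutant a replicate block gave 20 and median centring 30.

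In leaves without ABA the double mutant gave the most calls against WT. AT5G13770, a pentatricopeptide repeat protein, was lower by -2.90 (5.65 ± 0.39 against 8.55 ± 0.14, adjusted p = 0.00132) in every fit with an array left out, and in gpa1 by -2.33 (adjusted p = 0.0103). IQD31 (-2.56), the chloroplast-encoded rpl22 (-2.49) and AT2G34620 (-2.30) were lower in the double mutant and CML37 (2.12) and AT1G13340 (2.05) higher. AT5G63180, of the pectate lyase type, was lower in gpa1 (-2.04, adjusted p = 0.00833), as was AT1G63750 (-2.00, adjusted p = 0.0232, with -1.12 in the double mutant at adjusted p = 0.0585). Calls were lost in 3 of 6 fits with an array left out for AT5G13770 in gpa1 (up to 0.108), 2 for AT5G63180 (up to 0.0944) and 4 for AT1G63750 (up to 0.26). In the double mutant they were lost in 2 for IQD31 (up to 0.0799), 5 for rpl22, 3 for AT2G34620 (up to 0.077), 4 for CML37 (up to 0.185) and 2 for AT1G13340. Averaging over both treatments ended each of these calls (up to 0.458), and fits of only the groups compared ended all but those of IQD31 and AT2G34620 (up to 0.315).

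Of 33 lists 3, 3 and 9 passed for genotype in leaves of agb1, gpa1 and the double mutant, and none with an estimated correlation. In the double mutant ATG8 genes rose in 2 of 9 cases and ubiquitin-specific proteases fell in 2 of 12, with nuclear photosynthesis genes falling in 1 of 23 (camera adjusted p = 0.00106 for each, and adjusted p = 0.57 with an estimated correlation). The touch list rose in 1 of 5 there, and in 3 when adjusted over the list alone (median 0.68, adjusted p = 0.00975, and adjusted p = 0.189 with an estimated correlation). Without WT EtOH replicate 1 the calls of the touch (0.0539) and photosynthesis (0.0601) groups were lost, and without double mutant EtOH replicate 2 that of touch (0.123). In gpa1 nuclear photosynthesis genes had a median of -0.54 with none of 23 passing (adjusted p = 7.45e-07, and adjusted p = 0.736 with an estimated correlation). In agb1 their median was -0.25 (adjusted p = 0.00468, and adjusted p = 0.73 with an estimated correlation), a call lost without WT EtOH replicate 1 or agb1 EtOH replicate 2 (up to 0.388). The touch list passed in gpa1 with none of 5 passing by itself (median 0.35, adjusted p = 0.0233, and adjusted p = 0.269 with an estimated correlation), lost without WT EtOH replicate 1 or gpa1 EtOH replicate 3 (up to 0.194), and did not pass in agb1 (adjusted p = 0.429).

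In guard cells 3, 3 and 4 lists passed for genotype, and none with an estimated correlation. Nuclear photosynthesis genes had medians of 0.19, 0.39 and 0.30 in agb1, gpa1 and the double mutant with none of 23 passing (adjusted p = 0.00513, 1.87e-05 and 0.00425, and adjusted p = 0.584, 0.691 and 0.814 with an estimated correlation). These calls were lost without WT EtOH replicate 3 (0.75, 0.0548 and 0.496). The first was lost without agb1 EtOH replicate 2 too, and the last without double mutant EtOH replicate 3. The fixed ABA-induced list passed in the double mutant (median 0.63, adjusted p = 0.0375, and adjusted p = 0.185 with an estimated correlation), with 0 of 5 genes called by limma and 2 over the list alone. That call was lost without any 1 of WT EtOH replicates 2 and 3 and double mutant EtOH replicates 1 and 3 (up to 0.343) and without dim probe sets. The list did not pass in agb1 (adjusted p = 0.223) or gpa1 (adjusted p = 0.075). Mitochondrion-encoded genes were lower in gpa1 (median -0.35, adjusted p = 7.78e-05, and adjusted p = 0.691 with an estimated correlation) in every fit with an array left out, with none of 15 passing.

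The double mutant gave 1395 calls in leaves (435 higher, 960 lower) and gpa1 23, all lower. Limma called 0 probe sets in agb1, with 1585 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0928. No overlap was seen at 25.7, 16.8 and 10.7 percent of probe sets against 10 percent by chance. Single arrays moved these counts. The double mutant gave 87 and 765 without WT EtOH replicates 1 and 3, and 149, 2312 and 42 without its own replicates 1, 2 and 3. For gpa1 the counts were 2, 90 and 12 without WT EtOH replicates 1, 2 and 3, and 1, 2 and 399 without its own, and agb1 gave 40 without its replicate 2. Averaging over both treatments gave 1, 1 and 40 in agb1, gpa1 and the double mutant, and only the groups compared gave 0 in gpa1 (2609 unadjusted) and 703 in the double mutant. All 48 arrays in 1 fit gave 17, 343 and 2775, and array weights 2119 in gpa1 and 4020 in the double mutant. Trend and robust moderation gave 52 in gpa1. Median centring turned the split of the double mutant to 584 higher and 729 lower (all-gene median from 0.04 to 0.17, a shift of 0.13), and quantile normalization gave 5 higher and 22 lower in gpa1.

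The effects of the 3 mutants shared the WT arrays they were compared with. In leaves they correlated at 0.838 to 0.889. Simulated arrays without any effect gave 0.476 on average and up to 0.892, so that the observed values lay inside the simulated range, near its high end. Their covariances in leaves were 0.0945 (agb1 and gpa1), 0.138 (agb1 and double) and 0.161 (gpa1 and double) against a simulated mean of 0.0393. In guard cells they were 0.0171, 0.04 and 0.0383 against 0.0326. No range was taken for the simulated covariances. With 1 effect taken from EtOH arrays and the other from ABA arrays, which share no WT array but in guard cells share the deviations of paired arrays, the leaf values were -0.268 (agb1 and gpa1), -0.152 (agb1 and double) and -0.198 (gpa1 and double), inside the range of -0.385 to 0.462 simulated with paired arrays (mean 0.0909). In guard cells the shared values were 0.257, 0.66 and 0.517 against 0.531 simulated (up to 0.843), and the separate ones 0.0912, 0.386 and 0.347, inside -0.431 to 0.444 (mean 0.173).

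The double mutant was also compared with the sum of the 2 single mutants. In guard cells AT1G63750 was above the sum by 1.72 (adjusted p = 0.0177) and probe set 253271_s_at below it (-3.62, adjusted p = 0.00694). These were the 2 calls of limma (564 unadjusted). The call of AT1G63750 was lost without any 1 of WT EtOH replicates 1 and 3, gpa1 EtOH replicates 1 and 2 and the 3 double mutant arrays (adjusted p up to 0.0987), each leaving 1 call, and in fits of only the groups compared (0.572) and of all 48 arrays (1). Median centring gave 1 higher and 2 lower. In leaves limma called 0 (421 unadjusted, lowest adjusted p = 1). Lists passed without any member called. Nuclear photosynthesis genes lay below the sum in guard cells (median -0.33, adjusted p = 0.00313, and adjusted p = 0.656 with an estimated correlation) and above it in leaves (0.19, adjusted p = 0.00177, and adjusted p = 1 with an estimated correlation), each lost in 2 of 12 fits with an array left out (up to 0.265 and 0.333). Mitochondrion-encoded genes lay above it in guard cells (0.32, adjusted p = 0.0101, and adjusted p = 0.656 with an estimated correlation), lost in 5 of 12 (up to 0.296).

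The effects of the mutants were also compared between guard cells and leaves. AT2G22320 had the lower effect of agb1 in guard cells (-2.23, adjusted p = 0.00744), but stood at 3.14 in WT and 3.13 in agb1 leaves, near the lowest value of all arrays (2.42), where no drop of that size could be seen, so that the test restates the drop in guard cells. AT5G13770 was lower than WT in leaves of gpa1 and the double mutant. It had the higher signed effect in guard cells for gpa1 (3.04, adjusted p = 0.00333) and for the double mutant (3.33, adjusted p = 7.79e-04). AT5G63180 did so for gpa1 (2.07, adjusted p = 0.00409), where its guard cell levels of 4.18 in WT and 4.21 in gpa1 left little room for a drop, and AT2G34620 (2.77) and AT1G19835 (2.62) for the double mutant. Fits of only the groups compared ended the calls of AT2G22320 (0.946), AT5G13770 in gpa1 (0.0601) and AT5G63180 (0.16). Limma called 1 probe set for agb1 (1222 unadjusted), 146 for gpa1 (86 higher) and 751 for the double mutant (498 higher). Median centring gave 88 higher and 104 lower for gpa1 and 336 and 500 for the double mutant, moving the all-gene medians of the 3 tests by 0.105, 0.105 and 0.196. Leaving out 1 array moved these last counts. For agb1 they were 4 and 0 without guard cell WT EtOH replicates 2 and 3, 2 without guard cell agb1 replicate 3, 2 and 5 without leaf WT EtOH replicates 1 and 2, and 2, 5 and 2 without the 3 leaf agb1 arrays. For gpa1 they were 82 and 13 without guard cell WT EtOH replicates 1 and 3, 35 and 25 without guard cell gpa1 replicates 1 and 2, 19 and 334 without leaf WT EtOH replicates 1 and 2, and 21, 20 and 459 without the 3 leaf gpa1 arrays. For the double mutant they were 216 without guard cell WT EtOH replicate 3, 339 and 256 without its guard cell replicates 2 and 3, 176 without leaf WT EtOH replicate 1, and 321, 1222 and 192 without its 3 leaf arrays. Without guard cell WT EtOH replicate 3 the call of AT2G22320 was lost (0.0501).

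Of 33 lists 3, 4 and 8 passed for the effects of agb1, gpa1 and the double mutant between sample types, and none with an estimated correlation. Nuclear photosynthesis genes had the higher effect in guard cells in all 3, with medians of 0.48, 0.79 and 0.86 (adjusted p = 1.8e-05, 6.15e-10 and 2.41e-05, and adjusted p = 0.706, 0.628 and 0.54 with an estimated correlation) and 0, 0 and 2 of 23 passing. Mitochondrion-encoded genes had the lower one, with medians of -0.45, -0.65 and -0.67 (adjusted p = 7.12e-04, 0.00111 and 0.0222, and adjusted p = 0.706, 0.768 and 0.54 with an estimated correlation). All 6 calls held in every fit with an array left out, except that of mitochondrion-encoded genes in agb1 without leaf agb1 EtOH replicate 3 (0.185). The effects of the 3 mutants share the WT arrays of both sample types, so these calls are not independent of each other. The fixed touch list had the lower effect in guard cells in the double mutant (median -0.94, adjusted p = 0.00203, and adjusted p = 0.0562 with an estimated correlation) in every such fit, with 1 of 5 passing. Relative to median centring these medians were 0.38, 0.68 and 0.67 for photosynthesis, -0.56, -0.76 and -0.86 for mitochondrion-encoded and -1.14 for touch genes.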

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

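Of the tests in this part, the scaling tests on the score and on mitochondrion-encoded genes and the test on nuclear respiration genes were chosen before their results were seen, and all others, the scaling test on counts among them, only after the result they bear on was seen.

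WT leaves gave more ABA calls (8812) than leaves of agb1, gpa1 and the double mutant (3303, 2347 and 2311), although the direct tests of a different response called 0 probe sets in the fit used and up to 5009 (gpa1, array weights) in others. With each WT leaf array left out in turn the lowest count was 7570, which argues against a single array, and under other scalings it stayed at least 2.59 times the highest mutant count, which argues against scaling, while the 86.5 percent of the score difference left by scaling decides nothing, because only 0.152 of a shift common to all probe sets reaches the score. A candidate explanation is the genotype itself, since mutant leaves without ABA already lay nearer to the ABA state than WT on the score (exact permutation p = 0.00909, 3 against 9 arrays). That test uses the 3 WT solvent arrays that also enter the WT count, so it cannot part genotype from a difference of these arrays. With ABA the leaf difference was 0.0193 (exact permutation p = 0.614). Leaf effects of the mutants that share no WT array correlated at -0.268 to -0.152, inside the simulated range of -0.385 to 0.462. Stress from handling of the mutant leaves stays open, because the median of the touch, wound and early stress genes was above WT by at least 0.328 in every mutant. All mutants were compared with the same 3 WT solvent arrays, and a difference of these arrays as a set stays open too, on which the correlations of the mutant effects decide nothing, as 0.838 to 0.889 lay under the simulated high of 0.892. Their covariances (0.0945 to 0.161) lay above the simulated mean of 0.0393. They decide nothing either, since an effect common to the mutants and a difference of the WT arrays would both raise them.

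AT1G63750 was lower in gpa1 guard cells but not in the double mutant, and lay 1.72 above the sum of the single mutants. Loss of the alpha subunit whatever the beta subunit would lower it in the double mutant too, which stood at -0.215 in guard cells, so that this is argued against there, but at -1.12 in leaves (adjusted p = 0.0585, with gpa1 at -2.00), where it stays open. Wrong labels are argued against by probe sets picked on leaf arrays alone, as guard cell gpa1 arrays lay 3.25 or more under guard cell arrays without the mutation at 267375_at, and 3.43 or more above those of the double mutant at 253204_at. A difference of the gpa1 line in sequence or background could lower it in every setting, and the smallest drop of the 4 settings was -0.926. That leaves this last explanation open.

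Mitochondrion-encoded transcripts were higher in guard cells than in leaves. An effect on both kinds of organelle transcript would also raise the chloroplast-encoded genes, whose mean difference was -0.621, although a rise hidden by fewer chloroplasts is not excluded. Array scaling is argued against by the lowest median under another scaling, 3.93. More mitochondria in the guard cell samples might also raise nuclear genes of respiration, whose median was 0.481. A median under 0.5 was set to count against it and one above 1 for it, and the observed median fell just under the first bound. The interval of the median over the 14 measured members of 30 written (0.300 to 1.52, 98.7 percent) held both bounds. That interval was not part of the rule and reflects the spread among genes, not among arrays. Because the median lay so near the bound, this explanation, and a capture that raises only mitochondrial RNA, stay open.

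The ABA response differed between guard cells and leaves of WT at 5233 probe sets, higher in guard cells for AT3G17520 (6.40), AT5G45690 (5.81), EXPA4 (3.61) and PRN (1.65). The signed response was lower there for AT5G39520 (-5.80), AT3G14280 (-5.10), SWEET4 (-4.68), CML23 (-3.28), CML38 (-2.43) and STZ (-1.62). It was lower for XTH16 too (-3.52), but there because ABA lowered XTH16 in guard cells, while it did not pass in leaves. The list medians of this difference were -2.25 for touch, -1.46 for ATG8 and 1.06 for ubiquitin-specific protease genes. Genotype effects differed between guard cells and leaves at 1 probe set for agb1 (AT2G22320, -2.23, which in leaves lay too near the lowest values for a drop to be seen), 146 for gpa1 (AT5G13770 3.04, and AT5G63180 2.07, which lay low in guard cells) and 751 for the double mutant (AT5G13770 3.33, AT2G34620 2.77, AT1G19835 2.62). In guard cells the double mutant departed from the sum of the single mutants at 2 probe sets.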

How the results depend on the processing

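Every test in this part was set before the data were examined except the block within genotype, the gene groups from the annotation, and the list tests with an array left out. No named gene turned direction in any setting, and no list test did among the 127 that passed. Direction was not compared for the other list tests. The direction with more calls turned in several counts. Under median centring it turned for guard cells against leaves, for ABA in WT leaves, agb1 leaves and guard cells of agb1 and the double mutant, for the response difference of WT and for the effects of gpa1 and the double mutant between sample types. Other settings turned it for ABA in leaves of each mutant, for the response difference of WT and for the effects of agb1 and gpa1 between sample types. With median centring the splits were 8100 and 4122 for guard cells against leaves and 9231 and 3821 for ABA in WT leaves. Of counts and correlations 487 values stayed and 141 moved, of named genes 4667 calls stayed and 375 weakened, and of list tests 2038 stayed, 430 weakened and 35 strengthened. The list tests that stayed include those of fixed lists that passed in neither fit. The cause of a moved value was not tested, except that fewer genes were tested with 1 probe set per gene and fewer arrays entered smaller fits. With 2 arrays left in a group every fit could be made.

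With 1 probe set per gene the counts were 5067 for guard cells against leaves, 2228, 1702, 2300 and 1799 for ABA in guard cells of WT, agb1, gpa1 and the double mutant, 4740, 1641, 1129 and 1108 in leaves, and 2820 for their difference in WT. Genotypes gave 2 (agb1) and 4 (double) in guard cells, and 6 (gpa1) and 648 (double) in leaves. The gpa1 response in leaves gave 4, non-additivity 1 and the effects between sample types 57 (gpa1) and 334 (double).

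With only the groups compared, ABA gave 3017 in WT guard cells and 1557, 3967 and 1358 in mutant leaves. Genotypes gave 2, 8 and 2 in guard cells and 0 (gpa1, 2609 unadjusted by limma) and 703 (double) in leaves. Response differences in leaves gave 1758 (gpa1) and 255 (double), non-additivity 0 (771 unadjusted by limma), and effects between sample types 0 (agb1, 1110 unadjusted) and 3 (gpa1). Array weights gave 5806 for ABA in gpa1 leaves, 16, 13 and 184 for genotypes in guard cells, 2119 (gpa1) and 4020 (double) in leaves, 28, 5009 and 1255 for leaf responses, and 6, 2152 and 2769 for effects between sample types. All 48 arrays gave 9 (gpa1, guard cells), 17, 343 and 2775 (leaves), 5, 1392 and 493 (leaf responses) and 1 in each non-additivity test.

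Averaged over both treatments, in a fit without the pairs of EtOH and ABA arrays, genotypes gave 25, 47 and 133 in guard cells and 1, 1 and 40 in leaves. Median centring gave 30 (double, guard cells), 1 (agb1 response, guard cells) and 2 (agb1 effect between sample types), quantile normalization 1 (gpa1 response, leaves), dim probe sets left out 7 (double, guard cells) and 2 (agb1 effect between sample types), and trend and robust moderation 52 (gpa1, leaves). The replicate block gave 20 (double, guard cells) and 231 (gpa1 effect between sample types), and the block within genotype 5358 (ABA, agb1 guard cells) and 5, 921 and 6 (leaf responses). With an estimated correlation 6 fixed list tests, 3 of annotation groups and 1 of respiration passed, and 8 of respiration with fry. The p-values of respiration were unadjusted.

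With 1 array left out, ABA in leaves gave 2166 to 4045 (agb1), 1439 to 1788 (gpa1) and 1404 to 2421 (double). Response differences gave 0 to 180, 0 to 766 and 0 to 1 in leaves, and 0 to 1 for agb1 in guard cells. Genotypes gave 3 to 8, 2 to 4 and 5 to 17 in guard cells and 0 to 40, 1 to 399 and 42 to 2312 in leaves, non-additivity 1 to 3 in guard cells, and effects between sample types 0 to 5, 13 to 459 and 176 to 1222.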

Other observations

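The overlaps, the gene group and the genes put together in this part were chosen only after their values were seen, and the counts over other splits of the arrays before.

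Some genes that set guard cells apart from leaves in WT also answered to ABA in leaves. Both differences subtract the same 3 WT leaf arrays without ABA, so a low value there raises both. PUB19, a ubiquitin ligase, was higher in guard cells by 6.12 and rose by 5.98 with ABA in WT leaves. EXPA16 was higher in guard cells by 7.75 and rose with ABA in leaves by 4.72, and CML23 by 5.23 and 2.75. UGT73B5, a glucosyltransferase, was higher in guard cells by 6.08, and its ABA response in leaves is not given here. As a group built after the data were seen, UDP-glycosyltransferases rose with ABA in WT guard cells in 9 of 47 cases and fell in 4 (camera adjusted p = 0.0199, and adjusted p = 0.465 with an estimated correlation). That call was lost without guard cell EtOH replicate 2 (adjusted p = 0.0997) and without dim probe sets.

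The leaf profile of the double mutant without ABA overlapped with the ABA response of WT guard cells, which shares no array with it. Higher in both were 72 probe sets, with 37.18 expected by chance, and lower in both 224, with 111.5 expected, while 92 went opposite ways (correlation 0.136). The overlap rests on 1395 leaf calls, and with 1 leaf array left out these numbered 42 to 2312. The probe sets higher in both were then 5 to 116 and those lower in both 7 to 334, each above the number expected by chance (0.769 to 74.2 and 3.83 to 168), and the correlation was 0.11 to 0.143. These fits share most of their arrays, and the expected numbers take probe sets as independent, so chance is not excluded. Simulated leaf effects with no array in common correlated at -0.649 to 0.522 without any effect. Both effects there came from leaf arrays, so that this range decides nothing on a leaf effect against a guard cell one. Of the 4585 probe sets called for ABA in WT guard cells 2557 were called the same way in all 4 genotypes and 817 in WT alone, and of the 8812 in WT leaves 1519 and 5703. Called in WT alone means past the threshold only there. The direct tests of a different ABA response in a mutant called 0 probe sets in the fit used, though not in every fit. These are therefore not counts of responses particular to WT.

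Counts of calls were compared with those of other splits of the same arrays. With 2 groups every other split mixes arrays of both on each side. A real difference then enters the spread of the fit and lowers the count. Low counts there thus do not show what arrays without a difference would give. With 10 splits of 2 groups no share under 0.05 can be reached, and the real split gave the most calls (1 of 10) in all but 2 comparisons, those of gpa1 against WT in guard cells (2 of 10, the highest other 5) and of agb1 against WT in leaves (10 of 10, which tells nothing with 0 real calls, the highest other 3). Elsewhere the highest other split gave 3 calls for guard cells against leaves, 2 for ABA in WT guard cells, 29 in WT leaves, 1 in gpa1 leaves and 13 in double mutant leaves, 1 for gpa1 and 38 for the double mutant against WT in leaves, and 0 in the rest. Among splits that part every pair of EtOH and ABA arrays of the same number (4 for guard cells of each genotype and agb1 leaves), the highest other gave 0. These splits were fitted without pairs, where the real one gave 3571 for agb1 guard cells. They were not counted in the fit with a replicate block within genotype, which gave 5358 there.

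For differences of differences 100 splits were drawn. As many calls as the real 5233 for WT guard cells against leaves came in 7 of 100. The highest (7366) came from a split that swapped the treatment of all 6 leaf arrays and kept that of 4 guard cell arrays. These splits exchanged EtOH and ABA within a sample type. Swapping 1 type adds the 2 ABA responses instead of subtracting them, so the 7 of 100 tells nothing about chance. With 0 real calls every split reaches the count, so the 100 of 100 for response differences of mutants tells nothing, with highest other counts of 389, 1183 and 7 in guard cells and 917, 27 and 316 in leaves. Non-additivity was reached in 7 of 100 in guard cells (highest other 11) and, with 0 real calls and so telling nothing, 100 of 100 in leaves (highest other 3), and the agb1 effect between sample types in 31 of 100 (highest other 11). For that effect of gpa1 only the real split reached its count, 1 of 100 (highest other 129), and for that of the double mutant 2 of 100 (highest other 773). Splits of non-additivity and of effects between sample types can likewise add genotype effects that the real split subtracts.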
